A study of Mus musculus with 8 samples.

How the data were processed

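The series holds RNA-seq of pancreatic islets from male mice of mixed background aged 8 to 9 weeks, in 8 libraries that form 4 groups of 2. In the BKO model, MIP1-CreERT, a tamoxifen-inducible Cre recombinase driven by an insulin promoter, removes Sirt6 from beta cells of adult mice, and the islets were taken 2 weeks after tamoxifen. Its 2 control libraries differ in genotype, per the labels: replicate 1 carries 1 floxed and 1 wild-type Sirt6 allele and replicate 2 carries wild-type alleles. In the EKO model, Ngn3-Cre acts in the endocrine progenitors of the pancreas, so that all islet endocrine cells descend from cells that expressed the recombinase, and its controls carry Ngn3-Cre with wild-type Sirt6. Isolated islets recovered for 4 h in medium with 10% serum, and libraries were made from about 100 ng of total RNA with a stranded poly(A) kit. The labels name a pair of sequencer models without saying which library ran on which. A sequencing batch may or may not coincide with the model, and cannot be placed here. The 2 BKO control libraries must come from different animals, since their genotypes differ. For the other groups nothing in the labels says that replicates came from separate animals. The p-values measure only the spread between these samples, which may be technical in those groups.

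The authors deposited a table of raw counts, whole reads per gene symbol, for the 8 libraries, and the submitters' processing notes name TopHat, HTSeq and the mouse build mm9; the versions are not given in the sources used here. Whether the counting used strand is not given either. The last rows of that table are HTSeq's classes for reads that name no gene, and they were kept out of library sizes and tests. Reads aligned to more than 1 place made up 31.6% to 39.7% of each library's total, reads outside annotated genes 8.19% to 11.1%, and reads that fell on several genes 0.105% to 0.127%. Because reads with several alignments were not counted to genes, values of genes with near-identical copies (most ribosomal proteins, Hspa1a and Hspa1b, Gbp8, Rps4y2) are uncertain. The table lists 22609 symbols, of which 25 were turned into dates by a spreadsheet and could not be traced to a gene by name. All 8 columns of the table were matched to a library by name. The reference annotation at hand was of another build than mm9, so no coordinates are given, and it was used (GRCm38.p6) for the order of genes around Sirt6 alone.

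The authors also deposited a table of their own results for each model, with a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers. The tool and the rule that selected the genes are not stated. These values are shown as the authors' and entered no test.

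From the counts, differences were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F test (glmQLFit and glmQLFTest) with TMM scaling and filterByExpr, whose count minimum was 10. All 8 libraries entered the same fit of 4 groups, without covariates, and shared its estimate of the spread, with 4 residual degrees of freedom. This left 15041 genes, which held at least 99.97% of gene reads in every library. The common biological coefficient of variation was 0.431 and the prior degrees of freedom 2.44. The adjusted p is the Benjamini-Hochberg value over all genes tested, and 0.05 was the threshold. The contrasts were BKO against its controls, EKO against its controls, the difference between these effects, and the BKO controls against the EKO controls. Levels are given as CPM of the TMM-scaled libraries. All fold changes and standard errors without a named tool come from this fit, and n is 2 libraries per group throughout.

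Before the data were examined, 27 lists of genes were fixed (580 symbols, 573 in the table, 562 tested), covering beta cell identity, the secretory machinery, alpha cells, delta, PP and epsilon cells, beta cell disallowed genes, progenitor and dedifferentiation genes, ChREBP targets, glycolysis, the unfolded protein response, oxidative stress, p53 and apoptosis, the cell cycle, NF-kB and cytokine response, interferon response, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, fatty acid oxidation and PPAR targets, growth hormone and prolactin response, immediate early and heat shock genes, and markers of acinar, duct, endothelial, stellate, immune, Schwann and red blood cells. The 26 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with an estimated correlation. The alternatives were fixed before the data were examined too: scaling by DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, fits of 4 libraries, the replicate number as a block, acinar genes left out or their mean level as a covariate of the gene tests, and each library left out in turn. Chosen after seeing the data were robust moderation of the spread, a fit without the EKO-model libraries numbered 1, the acinar covariate in the list tests, and the count of genes at an unadjusted p under 0.05 in both models.

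The rule for named genes was also fixed in advance. It took Sirt6 and Txnip, the 6 largest changes each way among genes past the threshold, and from each list up to 2 members past the threshold or else its member of smallest p. Because it named few genes beyond the lists, the 12 genes of smallest p with a mean CPM of at least 5 were added for each comparison, and these, like any other gene named outside the rule, were chosen after their values were seen.

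The tests were checked on simulated counts with the means, depths and spread of the real libraries and 50 genes changed at each of 4 fold sizes per knockout group. In the simulation of the BKO comparison, edgeR on 14839 genes recovered 4% of 2-fold, 46% of 4-fold, 64% of 8-fold and 84% of 16-fold changes, with 6 false calls among 105. In that of the EKO comparison it recovered 4%, 34%, 68% and 80%, with 5 false calls among 98. DESeq2 on 15041 genes recovered 18% of 2-fold and 78% of 4-fold changes for BKO, and 24% and 66% for EKO, with 83 false calls among 225 and 69 among 204. In this simulation its calls thus included more false ones than its threshold states. The simulation gave each unchanged gene the same mean and spread in all groups, which the real libraries need not share. Of unchanged genes 4.92% had an unadjusted p under 0.05 with edgeR for BKO, against 147 of 15041 genes in the real data. The shares of false calls and of changes recovered therefore need not hold for the real data. The simulated spread was the one that edgeR fitted, so the comparison of the tools is not neutral. In the BKO simulation camera called the list that had been shifted and no other, and in the EKO simulation, where no list was shifted, it called 0. Genes were simulated independently of each other, so this check cannot show how camera with the preset correlation does on lists whose members move together. In the real data the estimated correlation reached 0.857 (acinar cells). Figures were drawn with matplotlib 3.10.9.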

Results

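Poly(A) RNA of isolated islets was sequenced in 4 groups of 2 libraries: BKO, in which Sirt6, a chromatin deacylase of the sirtuin family, was deleted from adult beta cells with MIP1-CreERT, EKO, in which it was deleted with Ngn3-Cre from the endocrine lineage on, and the controls of each model. Reads assigned to genes numbered 43198451 and 37302246 in the BKO controls, 38029994 and 44442165 in BKO, 23673180 and 22330252 in the EKO controls and 22592798 and 22662190 in EKO. The insulin genes Ins1 and Ins2 took 13.8% to 25.1% of these reads. Replicates differed far beyond sampling noise, with a chi-square per degree of freedom of 72.0 in the BKO controls, 92.6 in BKO, 236 in the EKO controls and 136 in EKO, so none was a library deposited more than once.

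Sirt6 itself was measured in every library. Its level was 18.8 and 12.6 CPM in the BKO controls and 16.8 and 22.8 CPM in BKO, and 24.4 and 17.0 CPM in the EKO controls and 24.2 and 21.6 CPM in EKO. The log2 fold change of Sirt6 was 0.34 ± 0.30 (SE) in BKO and 0.15 ± 0.30 in EKO, with an adjusted p of 1 in each. Gene-level counts include exons outside the floxed part, so this measurement checks nothing about the genotype labels. Without 1 library at a time the BKO value was 0.65 (BKO control replicate 1), 0.078 (BKO control replicate 2), 0.54 (BKO replicate 1) and 0.097 (BKO replicate 2). The EKO value was 0.40 (EKO control replicate 1), -0.091 (EKO control replicate 2), 0.066 (EKO replicate 1) and 0.22 (EKO replicate 2).

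The first comparison asked which transcripts differ in islets 2 weeks after Sirt6 was deleted from adult beta cells. The labels do not say whether the controls received tamoxifen, so any effect of the drug is not separated from that of the deletion here. Ambp, the precursor of the plasma proteins alpha-1-microglobulin and bikunin, was at 17.8 and 21.3 CPM in the controls and at 62.9 and 74.4 CPM in BKO, a log2 fold change of 1.81 ± 0.17 (SE, n = 2 per group, adjusted p = 0.398). Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, was at 24.1 and 17.3 CPM in the controls against 54.4 and 77.1 CPM in BKO. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 265 and 297 CPM against 625 and 649 CPM, and Krtap13-1, a keratin-associated protein gene, at 5.23 and 6.96 CPM against 32.1 and 31.6 CPM. Log2 fold changes were 1.67 ± 0.31 for Th, 1.18 ± 0.19 for Lars2 and 2.39 ± 0.31 for Krtap13-1. Specc1 (1.66 ± 0.26), Apod (1.73 ± 0.34), Slc5a10 (2.81 ± 0.57), Krt80 (1.90 ± 0.40) and Fxyd6 (0.98 ± 0.21) were also higher in both BKO libraries than in both controls. Among lower values, the prohormone convertase Pcsk1 had a log2 fold change of -0.57 ± 0.20, with 924 and 1052 CPM in the controls and 765 and 569 CPM in BKO.

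None of these genes passed the main test. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 15041 genes, limma-voom called 0, and 147 genes had an unadjusted p under 0.05 in edgeR (106 higher, 41 lower), fewer than the 752 that chance gives at that threshold. The fit shares its estimate of the spread with the EKO model, whose replicates differed more (chi-square per degree of freedom of 236 and 136, against 72.0 and 92.6). The count of 147 is thus no measure of how little changed in BKO. This count was 72 without BKO control replicate 1, 244 and 250 without EKO control replicates 1 and 2, 511 in a fit of the 4 libraries of the model, 523 without the EKO-model libraries numbered 1, and 1078 with the mean acinar level as a covariate. DESeq2 called 10 genes, all higher in BKO, among them Ambp, Krtap13-1, Lars2, Specc1, Th, Slc5a10 and Ghrl. On simulated data 83 of 225 DESeq2 calls for this comparison were false, a share that need not hold for the real calls.

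Txnip, the thioredoxin-interacting protein and a glucose-induced ChREBP target, was at 205 and 308 CPM in the BKO controls and at 411 and 523 CPM in BKO, a log2 fold change of 0.87 ± 0.48 (SE, adjusted p = 1). The ghrelin gene Ghrl, from the list of delta, PP and epsilon cells, was at 0.263 and 0.440 CPM in the controls against 4.98 and 2.24 CPM in BKO, and was the only member of that list past the threshold when adjusted over the list alone. Bid, a pro-apoptotic BCL2 family gene, was at 18.5 and 18 CPM against 23.8 and 24.0 CPM, with a log2 fold change of 0.39 ± 0.17 (adjusted p = 1). C1qa, a complement gene of macrophages, was at 31.8 and 37.4 CPM against 83.3 and 70.6 CPM, and Cxcl10, a chemokine induced by interferon, at 168 and 138 CPM against 466 and 228 CPM, with adjusted p of 1 for each. No member of any list passed over all genes in BKO with edgeR, and among members only Ghrl passed with DESeq2. The counts at an unadjusted p under 0.05 were 1 for the cell cycle list, 2 for immediate early and heat shock genes and 0 for acinar cells.

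Of the gene lists, markers of acinar cells fell in BKO by the camera test with a preset correlation, with 26 of 28 members lower and a median log2 fold change of -2.07 (adjusted p = 6.72e-11, and 0.998 with an estimated correlation). Cpa1, a pancreatic carboxypeptidase, was at 44.8 and 57.8 CPM in the controls against 19.4 and 4.07 CPM, and Prss2, a trypsinogen gene, at 83.8 and 64.2 CPM against 26.0 and 7.12 CPM. The cell cycle list rose, with 21 of 28 members higher and a median of 0.41 (adjusted p = 0.00227, and 0.998 with an estimated correlation), and Cdc20, an activator of the anaphase-promoting complex, had the smallest p among its members, at 1.27 and 1.92 CPM against 3.86 and 3.51 CPM. The list of immediate early and heat shock genes fell, with 15 of 21 lower and a median of -0.30 (adjusted p = 0.00979, and 0.998 with an estimated correlation), led by the heat shock gene Hspa1a at 23.8 and 6.21 CPM against 1.27 and 3.20 CPM. With an estimated correlation no list was called. The mean log2 CPM of the cell cycle list was 2.23 and 2.00 in the controls and 2.95 and 1.94 in BKO, and without BKO replicate 1 its direction turned to lower (adjusted p = 0.376). For the immediate early and heat shock genes the adjusted p was 0.308 without that library, and without BKO control replicate 2 it was 0.107 for the cell cycle and 0.0674 for these genes. With the mean acinar level as a covariate the immediate early and heat shock genes turned to higher (adjusted p = 0.00809).

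The second comparison asked the same of islets in which Sirt6 was absent from the endocrine lineage from its origin. Ambp rose in EKO from 27.0 and 29.7 CPM in the controls to 925 and 954 CPM, a log2 fold change of 5.05 ± 0.20 (SE, n = 2 per group, adjusted p = 0.00150) or 33.2-fold. Th was at 38.1 and 29.2 CPM in the controls and at 279 and 421 CPM in EKO (3.38 ± 0.33, adjusted p = 0.194). Nqo1, the quinone reductase induced by oxidative stress, was at 6.42 and 9.53 CPM against 34.3 and 78.3 CPM (2.82 ± 0.42, adjusted p = 0.627). Lower values were seen for Tmtc1, a mannosyltransferase gene of the endoplasmic reticulum, at 91.7 and 86.9 CPM against 32.4 and 27.8 CPM (-1.57 ± 0.17, adjusted p = 0.194), and for Ank2, which encodes ankyrin-B, at 191 and 135 CPM against 35.6 and 45.3 CPM (-2.01 ± 0.26, adjusted p = 0.413).

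Other genes at the smallest p in EKO were the tight junction gene Inadl (log2 fold change 1.35 ± 0.16), the neurofilament gene Nefm (1.84 ± 0.27), Mapt, which encodes the microtubule protein tau (1.09 ± 0.17), Thsd4 (1.41 ± 0.22), Rps4y2 (2.00 ± 0.30) and Fxyd6 (1.32 ± 0.21), none of which passed. Pdk4, a kinase that restrains pyruvate dehydrogenase, was at 45.3 and 35.6 CPM in the controls and at 14.3 and 9.55 CPM in EKO (-1.76 ± 0.30, adjusted p = 0.627). Txnip was at 144 and 239 CPM against 313 and 782 CPM (1.52 ± 0.49, adjusted p = 1). The transferrin receptor gene Tfrc was at 242 and 208 CPM against 114 and 83.0 CPM, and the lipoprotein lipase gene Lpl at 250 and 377 CPM against 140 and 110 CPM.

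edgeR called Ambp alone in this comparison, as did limma-voom, with 556 genes at an unadjusted p under 0.05 (318 higher, 238 lower) against 752 by chance. That count was on either side of 752 among the alternatives, with 379 without BKO control replicate 2, 1103 and 1621 without EKO control replicates 1 and 2, 783 without EKO replicate 1, 254 in a fit of the 4 libraries of the model, 1119 without the EKO-model libraries numbered 1 and 1028 with the acinar covariate. DESeq2 called 90 genes, 56 higher and 34 lower, including every gene named so far for EKO except Txnip and Sirt6. On simulated data 69 of 204 DESeq2 calls for this comparison were false, a share that need not hold for the real calls. In a fit of the 4 libraries of the EKO model alone the adjusted p of Ambp was 0.382 at a log2 fold change of 5.05.

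**Figure D1:**
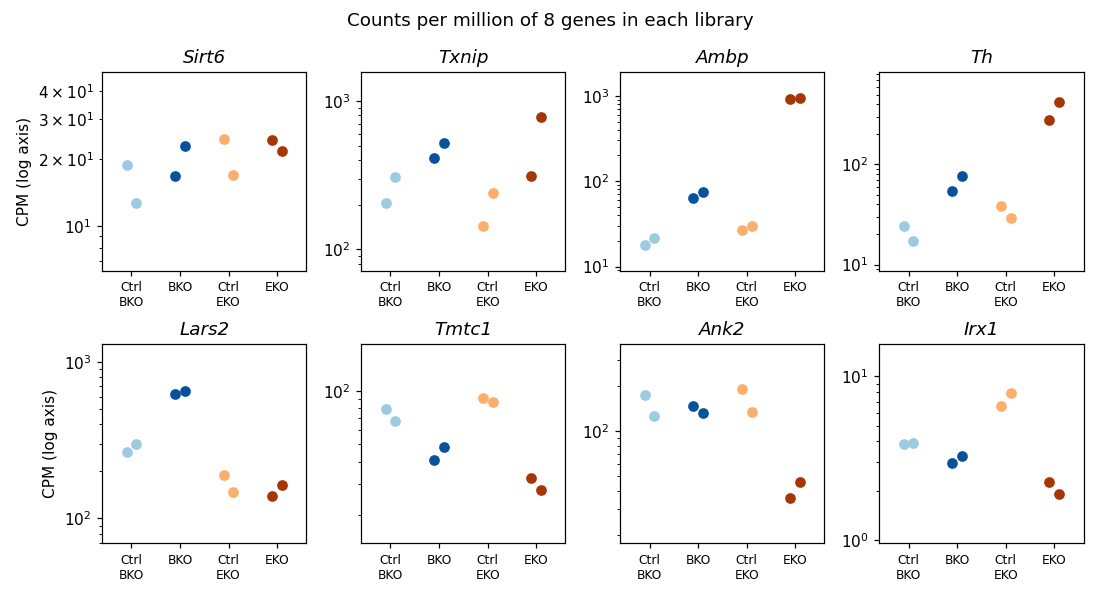
CPM (log axis) of 8 genes in each of the 8 libraries, with 1 point per library in the order of replicate number within each group. Ambp lay at 925 and 954 CPM in EKO and at 62.9 and 74.4 CPM in BKO, above 17.8 to 29.7 CPM in all controls, while Sirt6 ranged from 12.6 to 24.4 CPM over all libraries.

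Alpha cell markers fell in EKO by camera with the preset correlation, with 9 of 10 members lower and a median log2 fold change of -0.87 (adjusted p = 2.68e-05, and 0.444 with an estimated correlation). Irx1 and Irx2, transcription factors of alpha cells, passed when adjusted over the list alone and with DESeq2, but not over all genes with edgeR. Irx1 was at 6.54 and 7.85 CPM in the controls against 2.28 and 1.92 CPM in EKO, and Irx2 at 16.3 and 17.7 CPM against 7.31 and 3.79 CPM. The glucagon gene Gcg was at 27810 and 36985 CPM against 22054 and 8892 CPM. The mean log2 CPM of the list was 5.44 and 5.91 in the EKO controls, 4.87 and 5.04 in EKO and 4.84 to 5.04 in the 4 libraries of the BKO model, so the EKO libraries lay within the range of the other model. Without EKO control replicate 2 the adjusted p of the list was 0.0718.

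The p53 and apoptosis list rose in EKO, with 19 of 23 members higher and a median of 0.43 (adjusted p = 1.28e-04, and 0.444 with an estimated correlation), and its adjusted p was 0.117 without EKO replicate 1. Its leading member, Bid, was at 11.6 and 13.5 CPM against 21.3 and 22.1 CPM and was called by DESeq2 but not by edgeR. Acinar cell markers fell, with 25 of 28 lower and a median of -1.84 (adjusted p = 1.09e-04, and 0.964 with an estimated correlation). The acinar list rested on a pair of libraries: its mean log2 CPM was 6.81 and 3.47 in the controls and 5.41 and 2.25 in EKO, and its direction turned to higher without EKO control replicate 1 (adjusted p = 0.756) and without EKO replicate 2 (0.962).

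A further 4 lists were near the threshold in EKO by camera with the preset correlation. Oxidative stress genes rose (18 of 21 higher, median 0.19, adjusted p = 0.0349, and 0.964 with an estimated correlation), and Nqo1 was their only member past the threshold when adjusted over the list alone. Fatty acid oxidation and PPAR targets rose (17 of 24, median 0.19, adjusted p = 0.0349, and 0.863 with an estimated correlation), with Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, at 66.1 and 54.9 CPM against 85.8 and 102 CPM. Cholesterol synthesis genes fell (18 of 22, median -0.17, adjusted p = 0.0349, and 0.964 with an estimated correlation). NF-kB and cytokine genes fell (23 of 24, median -0.98, adjusted p = 0.0495, and 0.964 with an estimated correlation), with the chemokine gene Cxcl1 at 63.8 and 8.50 CPM against 8.19 and 3.93 CPM. For oxidative stress the adjusted p was 0.0509 and 0.0508 without BKO control replicates 1 and 2, 0.556 without EKO control replicate 2, 0.674 without EKO replicate 1, 0.0567 with the replicate number as a block and 0.103 without the EKO-model libraries numbered 1. Without EKO control replicates 1 and 2 and EKO replicate 2 in turn it was 0.156, 0.0873 and 0.572 for fatty acid oxidation and 0.0840, 0.178 and 0.962 for cholesterol synthesis, and with the acinar covariate 0.0675 and 0.249. The NF-kB call was lost without any of the 4 libraries of the BKO model (0.0508 to 0.0640) and without EKO replicate 2 (0.513), with DESeq2 size factors (0.0784), with acinar genes left out (0.0542) and with the acinar covariate (0.993). Its direction turned to higher without EKO control replicate 1 (0.00727) and without the EKO-model libraries numbered 1 (0.240).

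The remaining lists passed in neither comparison, with adjusted p by camera of 0.103 to 0.993 in BKO and 0.107 to 0.942 in EKO, where called lists are left out. The median log2 fold change of beta cell identity genes was -0.02 in BKO and -0.07 in EKO, and that of the secretory machinery -0.07 and 0.01. For islet cell types other than beta cells the BKO medians were -0.04 for alpha cells and -0.25 for delta, PP and epsilon cells, the latter at -0.38 in EKO. Beta cell disallowed genes had medians of -0.13 in BKO and -0.66 in EKO, progenitor and dedifferentiation genes -0.21 and -0.02, ChREBP targets 0.12 and 0.11, glycolysis and HIF1 targets 0.05 and -0.30, and unfolded protein response genes 0.06 and -0.20. Interferon response genes were at -0.15 and -0.17, oxidative phosphorylation at 0.04 and 0.00, ribosomal proteins at -0.04 and -0.09, and growth hormone and prolactin response genes at 0.09 and -0.19. Markers of duct cells were at -0.09 and -0.51, of endothelial cells at -0.08 and -0.13, of stellate cells and fibroblasts at -0.22 and -0.55, of immune cells at 0.24 and -0.28, and of Schwann cells and neurons at -0.48 and -0.26. In BKO the medians were 0.01 for oxidative stress, 0.07 for p53 and apoptosis, -0.22 for NF-kB, 0.09 for cholesterol synthesis and 0.01 for fatty acid oxidation, and in EKO 0.14 for the cell cycle and 0.19 for immediate early genes. Of the red blood cell markers only Alas2 was tested, at log2 fold changes of -3.06 ± 1.58 (SE) in BKO and 1.02 ± 1.73 in EKO. The median, the mean and the camera direction were not all of the same sign in BKO for beta cell identity, alpha cells, delta, PP and epsilon cells, ChREBP targets, oxidative stress, ribosomal proteins, fatty acid oxidation, immune, duct and Schwann cells, nor in EKO for the secretory machinery, progenitor genes, ChREBP targets, interferon response, growth hormone response, immediate early genes, duct and stellate cells.

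Many of these lists passed by camera when 1 library was left out, and the direction depended on which. In BKO the interferon list was called higher without BKO control replicate 1 (adjusted p = 0.0199) and lower without BKO control replicate 2 (0.00217). The cholesterol list was called higher in BKO without BKO control replicate 1 (4.98e-06) and without BKO replicate 2 (0.00355). In EKO 8 lists were called in opposite directions without EKO control replicate 1 and without EKO control replicate 2. Of these, beta cell identity was lower without the former (5.14e-05) and higher without the latter (0.00763). The other 7 were higher without the former and lower without the latter. They were interferon response (7.89e-04 and 0.00559), beta cell disallowed genes (2.76e-04 and 8.19e-07), ribosomal proteins (0.0364 and 0.00100) and immediate early and heat shock genes (0.00150 and 0.00765). Cell type lists among them were duct (1.89e-05 and 0.00449), stellate (1.06e-08 and 4.55e-04) and immune cells (0.0169 and 8.51e-05). Without EKO replicate 2, beta cell identity was called lower (0.00376), and immediate early genes (0.00494) and stellate cells (0.0186) higher. Without EKO replicate 1, immediate early genes were called lower (0.0207). A further 5 lists were called in only 1 direction. The cell cycle list was higher without BKO replicates 1 and 2 (0.0424 and 0.0423), EKO control replicate 1 (0.00288) and EKO replicate 1 (0.0207). Progenitor genes were higher without EKO control replicate 1 (0.00328) and EKO replicate 2 (0.0210). Endothelial cells were lower without EKO control replicate 2 (0.0118) and EKO replicate 2 (0.0200). Glycolysis (0.00124) and the unfolded protein response (0.00855) were lower without EKO control replicate 2. With the acinar covariate beta cell identity was called lower in BKO (1.34e-04) and in EKO (4.99e-05).

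**Figure D2:**
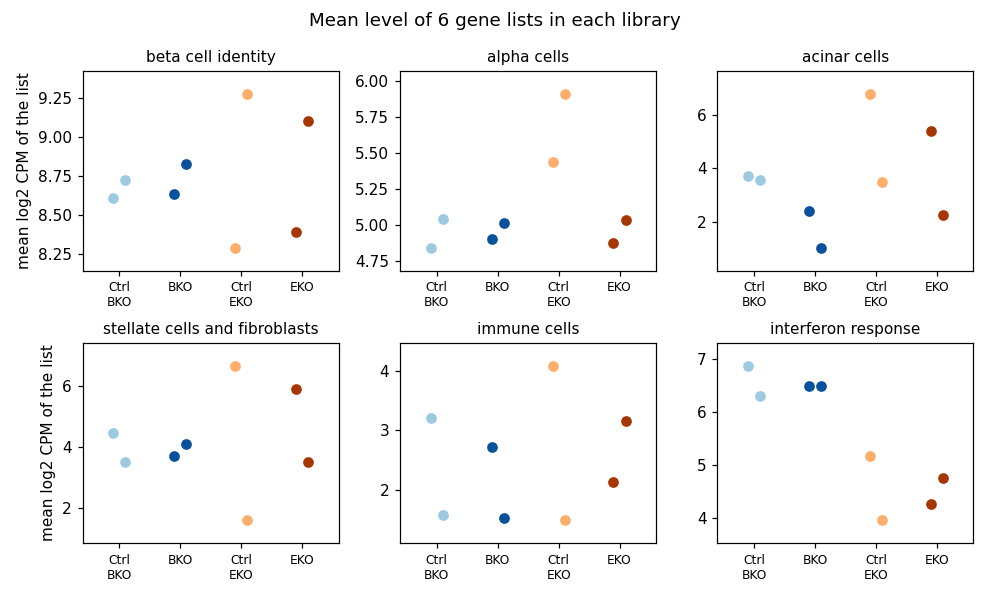
Mean log2 CPM of the members of 6 gene lists in each library, with 1 point per library in the order of replicate number. The replicates of the Ngn3-Cre model lay far apart for acinar cells (6.81 and 3.47 in the controls) and stellate cells (6.66 and 1.60), and the interferon list was higher in all libraries of the MIP1-CreERT model.

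Between the models, which share no library, 65 genes had an unadjusted p under 0.05 in both comparisons, and 64 of them moved in the same direction (98.5%, exact 95% interval 91.7% to 99.96%), with 51 higher and 13 lower. The interval treats genes as independent, which they are not, and another split of the same libraries, not by genotype, gave 271 genes in the same direction and 1 in opposite ones. Independent lists of these sizes would share 2.89 genes in the same direction. By adjusted p edgeR called 0 genes in both models and limma-voom 0, and DESeq2 called 6, among them Ambp, Th and Specc1. The median absolute log2 fold change of the 64 genes was 0.87 in BKO and 1.27 in EKO, and 44 of them had the larger value in EKO. Tmtc1 and Tfrc were among those lower in both, at log2 fold changes of -0.73 and -0.77 in BKO and -1.57 and -1.19 in EKO. Across all tested genes, which are not independent replicates, the fold changes of the models had a Pearson r of 0.202 and a Spearman rho of 0.333. The count of 64 fell without BKO control replicate 1. It rose without EKO control replicate 2 and without the EKO-model libraries numbered 1. With the replicate number as a block in fits of 4 libraries it was 186, against 15.9 for independent lists. With the acinar covariate it was 314, against 37.7. Each of these sets held 45 of the 64 genes, beside 10 and 11 genes in opposite directions.

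**Figure D3:**
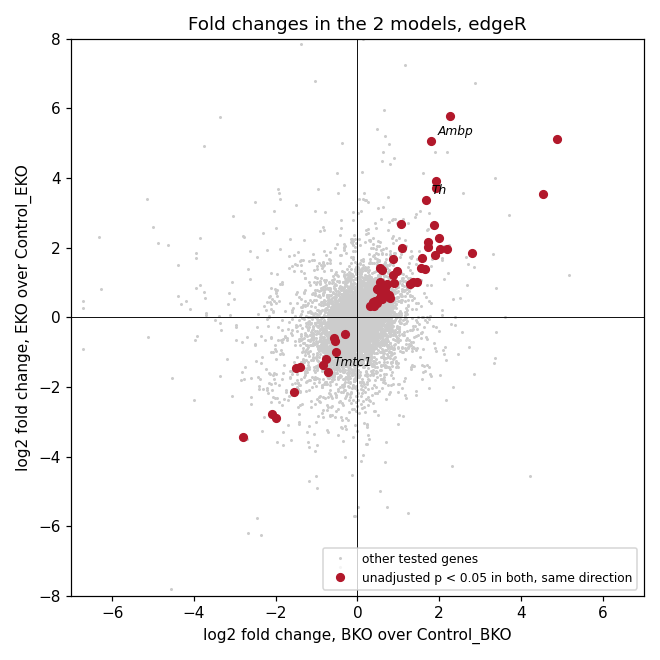
Log2 fold change of each tested gene in BKO (horizontal axis) and EKO (vertical axis), each against its own controls, with 6 genes outside the axes. Red points are the 64 genes at an unadjusted p under 0.05 in both models and in the same direction, of which 51 were higher and 13 lower.

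The third contrast tested whether the effect of losing Sirt6 differed between the models. edgeR called 0 genes and limma-voom 0, with 152 genes at an unadjusted p under 0.05 in edgeR. That count was 84 without BKO control replicate 1, 81 without BKO replicate 1, 584 and 596 without EKO control replicates 1 and 2, 313 without EKO replicate 1, 684 without the EKO-model libraries numbered 1 and 439 with the acinar covariate. Ambp had the smallest p, with an effect larger in EKO by 3.24 ± 0.24 on the log2 scale (SE, adjusted p = 0.0898). DESeq2 called 6 genes, among them Ambp and Ppm1e with the higher fold change in EKO and Ank2, Nxph1 and Lars2 with the lower one. Lars2 was at 191 and 147 CPM in the EKO controls and 139 and 164 CPM in EKO, and Ank2 at 175 and 127 CPM in the BKO controls and 148 and 132 CPM in BKO. For Txnip the difference was 0.65 ± 0.67 and for Sirt6 -0.19 ± 0.43, with an adjusted p of 1 for each. Camera with the preset correlation called 9 lists for this contrast, with the alpha cell list (median -1.03, adjusted p = 4.68e-06, and 0.438 with an estimated correlation) and the cholesterol list (median -0.28, adjusted p = 1.15e-04, and 0.787 with an estimated correlation) at the smallest p, and none was called with an estimated correlation.

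The authors' deposited table for BKO lists 99 genes, 62 higher and 37 lower, of which 70 have an adjusted p under 0.05 there. All 99 had the same direction in the edgeR fit, 45 had an unadjusted p under 0.05, 0 were called by edgeR and 10 by DESeq2. The authors' deposited table for EKO lists 243 genes, 129 higher and 114 lower, with 33 at an adjusted p under 0.05 there. Of these, 242 were matched by symbol, all 242 had the same direction in the edgeR fit, 218 had an unadjusted p under 0.05, 1 (Ambp) was called by edgeR and 84 by DESeq2. Both tables come from the same counts, so their agreement in direction is no independent evidence. In the authors' deposited tables Txnip has a log2 fold change of 0.61 in BKO and 0.83 in EKO, with adjusted p of 0.0688 and 0.892. The authors' deposited tables share 23 genes, all with the same direction, against 1.60 for independent lists.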

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

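The 8 genes that follow had, in both libraries of each knockout, values on one side of both controls in BKO and on the other side in EKO. If knockouts and controls lay apart by chance for 33.3% of genes in each model, independently, about 836 of 15041 would show that pattern, and 188 showed it. Fewer genes lay apart than that, 4528 in BKO and 3319 in EKO, so 836 is too high a reference. In both models and in the same direction, 1064 genes lay apart. The difference between the models was tested for each with edgeR's quasi-likelihood test, and the adjusted p was 1 for all 8. All but Ppm1e, Nxph1, Ang and Rnase4 were named by the rule for named genes fixed in advance. The rule fixed in advance for flagging was another, an adjusted p under 0.05 for the difference between the models. It flagged none of the named genes. The pattern of sides used here was not part of it and was added.

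The ghrelin gene Ghrl had an EKO effect minus BKO effect of -4.67 ± 1.05 (SE, log2), with 0.263 and 0.440 CPM in the BKO controls, 4.98 and 2.24 CPM in BKO, 4.44 and 8.55 CPM in the EKO controls and 1.31 and 3.89 CPM in EKO. Cd81, a tetraspanin gene reported as a marker of immature beta cells, differed by 1.34 ± 0.50, with 61.4 and 59.9 CPM against 43.1 and 57.2 CPM in the BKO model and 118 and 54.5 CPM against 190 and 169 CPM in the EKO model. Bhlha15, an acinar cell transcription factor, differed by -0.94 ± 0.34, and Emr1, a macrophage marker, by -2.78 ± 1.14, the latter with 22.2 and 3.67 CPM in the EKO controls. Ppm1e, a protein phosphatase gene, differed by 1.51 ± 0.27, with 36.3 and 39.6 CPM against 23.4 and 24.4 CPM in the BKO model and 11.4 and 14.6 CPM against 22.0 and 24.6 CPM in the EKO model. Nxph1, a neurexophilin gene, differed by -3.32 ± 0.65, with 1.18 and 1.89 CPM against 2.31 and 2.02 CPM in the BKO model and 6.87 and 5.86 CPM against 1.09 and 0.702 CPM in the EKO model. DESeq2 called the differences of Ppm1e and Nxph1 (adjusted p = 0.0125 and 0.0216). The neighbouring ribonuclease genes Ang and Rnase4, which share a promoter region, differed by 1.30 ± 0.30 and 1.67 ± 0.41, and Rnase4 was at 676 and 597 CPM against 390 and 521 CPM in the BKO model and at 414 and 609 CPM against 946 and 1386 CPM in the EKO model.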

How the results depend on the processing

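Of the named genes, 6 results turned direction under some alternative, and none of these 6 was past the threshold in any fit. The fit without the EKO-model libraries numbered 1, the robust fit, the acinar covariate in the list tests and the count of genes shifted the same way in both models were chosen after seeing the data. Causes of the shifts were not tested unless stated. With 1 library left in a group, that library is assumed to vary like the other groups.

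Sirt6 in EKO was -0.091 without EKO control replicate 2, within a range of -0.091 to 0.40 over the libraries left out. Alas2 in EKO was -0.36 with the acinar covariate and ranged from -0.96 (without EKO replicate 2) to 2.07 over the libraries left out, and Txnip between the controls was -0.013 with the covariate. Over the libraries left out, Txnip in the difference of the models ranged from -0.16 (without EKO replicate 2) to 1.17, Mgp in BKO from -0.76 to 0.12 (without BKO control replicate 2) and Sdf2l1 in EKO from -1.69 to 0.11 (without EKO control replicate 1).

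DESeq2 moved the counts of called genes most, to 10 for BKO, 90 for EKO, 6 for the difference, 216 between the controls and 6 in both models, and the called share of the authors' deposited lists to 10.1% and 34.7%. Fits of only 4 libraries called 0 genes for EKO, 0 between the controls and 0% of the deposited EKO list. Without a filter 7 genes were called between the controls, and with the acinar covariate 8. The acinar covariate raised the genes shifted the same way in both models from 64 (2.89 for independent lists) to 314 (37.7). It raised the lists called in BKO from 3 to 14, of which 1 was among the 3 and in the same direction. Without the EKO-model libraries numbered 1 the calls were 2 for EKO and 62 between the controls, with 150 genes shifted the same way, 13 lists in EKO and 0.826% of the deposited EKO list. An estimated correlation left 0 lists in BKO and 0 in EKO.

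Leaving out 1 library gave 1 to 2 genes for EKO, 0 to 5 between the controls, 27 to 97 shifted the same way, 0.413% to 0.826% of the deposited EKO list, 1 to 5 lists in BKO and 5 to 14 in EKO. The 14 lists in EKO were 12 higher and 2 lower without EKO control replicate 1 but 2 higher and 12 lower without EKO control replicate 2, and each set held 3 of the 7 lists called with all libraries, in the same direction. Beta cell identity went from lower (adjusted p = 5.14e-05) to higher (0.00763) between these fits. BKO and the difference stayed at 0. Ambp in EKO stayed past the threshold with any single library left out (adjusted p from 0.0142 to 0.0255) and lost it only in fits of 4 libraries (0.382, and 0.176 with the block).

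The replicate numbers of the labels give 2 pairs per model and nothing says that they mark a shared litter or day, so they share only a number. Deviations of same-numbered libraries correlated at 0.310 across genes in the BKO model and 0.492 in the EKO model. Across the models they correlated at 0.409 for the controls and -0.254 for BKO with EKO. For BKO with the EKO controls the value was 0.144, and for EKO with the BKO controls -0.090. A pair across models thus exceeded the BKO value, so these correlations cannot tell whether the number marks a real pair. With the number as a block of the fit of 8 libraries, 2 genes were called between the controls, and in fits of 4 libraries the block gave 3 genes for BKO, 0 for EKO and 0 between the controls, 186 shifted the same way, and 1.01% and 0% of the deposited lists. It changed no other count of calls by over 1.5 times. In fits of 4 libraries the block moved the genes at an unadjusted p under 0.05 from 511 to 552 for BKO and from 254 to 873 for EKO, and with 8 libraries it ended the call of oxidative stress in EKO (adjusted p = 0.0567).

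At 22330252 to 44442165 gene reads per library, the spread between replicates, not counting noise, sets the precision of all but low genes.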

Other observations

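Tests chosen after the result was seen were those of immune, stellate, duct, endothelial and Schwann cells carried over, of the alpha cell level in the EKO controls, of batch and of growth hormone signalling.

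The controls of the models, which no comparison of the study sets side by side, differed in several gene groups. Gbp8, an interferon-induced guanylate-binding protein gene, rose by 5.21 ± 0.23 (SE, log2, adjusted p = 0.00371) in the BKO controls over the EKO controls, from 6.25 and 7.53 CPM to 247 and 262 CPM, and was the only gene that edgeR called. At an unadjusted p under 0.05 there were 833 genes (433 and 457 without BKO control replicates 1 and 2, 1679 and 1752 without EKO control replicates 1 and 2, 549 in the fit of the 4 control libraries, 2663 without the EKO-model libraries numbered 1 and 1886 with the acinar covariate), limma-voom called 1 and DESeq2 216. Without BKO control replicates 1 and 2 in turn the adjusted p of Gbp8 was 0.0523 and 0.0593. The interferon response list rose by camera with the preset correlation, with 27 of 27 members higher, 19 when adjusted over the list alone, and a median of 1.84 (adjusted p = 1.36e-28, and 0.350 with an estimated correlation). NF-kB and cytokine genes rose (median 1.57, adjusted p = 1.17e-13, and 0.480 with an estimated correlation), with Icam1 at 213 and 150 CPM against 38.9 and 11.5 CPM. Lists of alpha cells (median -0.84), acinar cells (-2.69), endothelial cells (-0.37) and immune cells (-0.50) fell and oxidative stress genes rose (0.14), with adjusted p of 0.376 or more under an estimated correlation. By mean log2 CPM the acinar and immune falls rested on EKO control replicate 1 (6.81 and 4.08). EKO control replicate 2 (3.47 and 1.49) lay below both BKO controls (3.70 and 3.57 for acinar, 3.21 and 1.58 for immune cells).

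The growth hormone and prolactin list rose between the controls too (median 1.03, adjusted p = 1.11e-05, and 0.350 with an estimated correlation). Tph1, the serotonin synthesis enzyme induced by prolactin in beta cells, was at 25.5 and 335 CPM in the BKO controls and 198 and 89.7 CPM in BKO, against 0.123 and 0.0929 CPM in the EKO controls and 0.525 and 2.62 CPM in EKO. Cish, a feedback inhibitor of that pathway, was at 147 and 211 CPM in the BKO controls against 26.4 and 42.8 CPM, and Socs2 at 92.6 and 118 CPM against 28.2 and 28.3 CPM. DESeq2 called 5 of the 16 members and edgeR 0, with 4 past the threshold when adjusted over the list alone. The MIP1-CreERT transgene is known to carry a human growth hormone minigene, but growth hormone or prolactin receptor signalling in the MIP1-CreERT model cannot be told apart from cytokine signalling or a batch of the model. All 4 libraries of the MIP1-CreERT model lay above all 4 of the other for this list. Receptor signalling, cytokine signalling or a batch could each give that order, so it cannot decide between them. That order also says nothing on the size of the Tph1 difference, whose cause was not tested.

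Esr1 was at 555, 1475, 1696 and 1079 CPM in the libraries of the BKO model and at 0 to 0.494 CPM in those of the EKO model. CreERT proteins are fusions of Cre with the ligand-binding domain of the oestrogen receptor, which Esr1 encodes. The keratin-associated gene Krtap13-1 had 0 reads in all 4 libraries of the EKO model. Cwc22, a splicing factor gene with extra copies in some mouse strains, was at 105 and 76.0 CPM in the BKO controls, 20.7 and 16.7 CPM in BKO, 109 and 17.5 CPM in the EKO controls and 136 and 23.5 CPM in EKO, and has a log2 fold change of -1.61 in the authors' deposited table for BKO.

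For the higher interferon list in the BKO controls, sequencing depth is argued against, since the median was 1.83 after the BKO controls, 1.75 times as deep, were thinned to the depth of the EKO controls, against 1.84 before. Carried-over immune cells are argued against by a median of -0.50 for the immune cell list, though by mean level only EKO control replicate 1 lay above the BKO controls. A difference in handling or sequencing batch that followed the model cannot be told apart from it, because all 4 libraries of the MIP1-CreERT model lay above all 4 of the other. The labels do not say whether any batch did. Tamoxifen, the Cre driver and the genetic background stay open as biological differences, untested.

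For the 64 genes shifted the same way in both models, acinar and 5 other kinds of cell carried over with the islets were each tried as a covariate, by the mean level of their markers. In the model where the ratio was lower, the median absolute fold change was 1.01 times its value without the covariate for acinar and for immune cells. The ratio was 0.986 for stellate cells and fibroblasts, 0.996 for duct, 0.993 for endothelial and 1.0002 for Schwann cells and neurons. These ratios cannot decide on carried-over cells. The 64 genes were chosen for a small p, and so for little spread within groups, and the covariate is fitted from that spread alone. Strain DNA beside the floxed allele does not account for most of them, as 2 of 62 placed genes (Appl2 and Zfp781) lay within 50 tested genes of Sirt6, against 0.420 by size. Separate fits of the models, which share no spread, gave 57 of 60 genes in the same direction (95%, exact interval 86.1% to 99.0% if genes were independent). A shared spread does not set the direction of a fold change, so that share cannot decide on it. It could raise the count, but the 57 genes of the separate fits compare with 4.39 for independent lists. An excess was thus there without a shared spread, though only 39 of the 57 were among the 64. Of 18 ways to split the libraries 2 against 2 in each model, 6 gave at least the 64 genes of the real one, with 271 (and 1 in opposite directions) as the highest other, and 18 splits are too few for a share under 0.05. That split gives several times the real count and points to a structure of the samples other than genotype: it parts BKO control 1, BKO 1, EKO control 1 and EKO 2, with a mean log2 CPM of 3.29 for immune markers, from the others, at 1.68, and shares 0 genes with the 64.

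For the alpha cell list, lower in EKO, fewer cells of every non-beta type cannot be told apart from a change in alpha cells. By mean level the list's change differed from that of delta, PP and epsilon cells by -0.51 ± 0.51 (SE, log2) and from that of endothelial cells by -0.74 ± 0.61, each within 2 SE. The endothelial list changed by 0.024 in mean level, though 12 of its 17 members were lower, with a median log2 fold change of -0.13. A high alpha cell share in the EKO controls is a candidate explanation, since the mean level in EKO lay 0.0057 above that of the BKO model. Loss of Sirt6 from alpha cells, which Ngn3-Cre also targets, stays open as a biological explanation, untested.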
